A study of Mus musculus with 2 samples.

How the data were processed

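Thymocytes of 1 wild type sample and 1 sample homozygous for mutations of GATA sites 1 and 2 of NMe were loaded at 5000 cells per sample on the 10x Chromium system with the 3' v2 reagents and sequenced on an Illumina HiSeq, per the labels' protocols. The deposited values are raw UMI counts per cell barcode and gene symbol. Cell Ranger and the genome build mm10 were used, per the submitters' processing notes, with no version given in the sources used here. The tables held whole numbers for 27933 gene symbols. They held 1346 barcodes in wild type and 1737 in mutant, which is 26.9% and 34.7% of the cells loaded. The lowest totals were 1781 and 1416 UMIs, so a lower limit of UMIs per barcode differed between the libraries, and the step that set it is not stated in the sources used here. No cell type annotation was used.

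Barcodes with at least 400 detected genes and at most 10% of UMIs from mitochondrial genes were kept, which left out 5 wild type and 6 mutant barcodes. Scrublet, run in each library with an expected doublet rate of 4%, called 3 and 5 cells, which were left out, so that 3064 of 3083 barcodes remained. It called 0.26% of the cells, so uncalled doublets remain among the kept cells, and an alternative left out the highest scores. Each cell was scaled to 10000 UMIs and log transformed. The 2000 most variable genes were used, without Myc, mitochondrial and ribosomal protein genes, immune receptor segments, Xist, Y-linked and haemoglobin genes. With 30 principal components, 15 neighbours and Leiden clustering at resolution 1, both libraries together gave 17 clusters, with no batch integration. A cluster was named from marker lists fixed beforehand when at least 3 markers of a type were among its 50 leading genes, and names are used in the sense of X-like. Cluster 13, led by Xcl1 and other innate-like T and NK cell genes, and cluster 15, led by Cd74, H2-Aa and Cd79a, were left out of the 5 classes but are part of the values over all cells. No cluster of a class had more markers of another class than of its own among its 10 leading genes.

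UMIs were summed over the cells of each library and class and divided by the class total to give UMIs per 1000000 UMIs (CPM), with exact Poisson intervals. Ratios have exact conditional intervals, shares exact Clopper-Pearson intervals, and differences of shares Newcombe intervals, all at 95%. For 0 UMIs the fold is given against a floor of 3 UMIs. For each of 21 gene lists the median log2 ratio, with 5 CPM added to both sides, was taken over members with at least 20 CPM in at least 1 library. It was placed among the medians of 10000 random lists of the same size matched on level, which describes these libraries. The lists were MYC-activated ribosome biogenesis and growth genes, MYC network partners, DNA replication, mitosis, ribosomal proteins, NOTCH targets, T-lineage transcription factors, glycolysis, oxidative phosphorylation, amino acid transport and polyamines, translation factors and tRNA synthetases, apoptosis regulators, p53 targets, CDK inhibitors and quiescence, V(D)J recombination, T cell receptor and CD3, T cell receptor response, tissue dissociation and stress, interferon response, unfolded protein response, and cholesterol synthesis. Of the T cell receptor and CD3 list, 7 constant region genes such as Trac were not among the gene symbols. Its measured members were thus CD3 genes and signalling genes such as Lck and Zap70, with no receptor chain gene. The list called NOTCH targets also holds the receptors Notch1 and Notch3, the pathway genes Rbpj and Maml1, and the T cell genes Cd3d, Lef1 and Tcf7.

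Genes were named by a rule of size. Genes with at least 50 CPM in at least 1 library and at least 20 UMIs in both together were ranked by the log2 ratio with 5 CPM added, in classes with at least 100 cells in each library. The 12 highest and 12 lowest were named over all cells and in cycling cells, and the 6 highest and 6 lowest in DP, post-selection and SP cells. Mitochondrial, ribosomal protein, sex-linked, haemoglobin, immune receptor segment and unnamed genes were not ranked. Over all cells 2779 genes were ranked. In each list the 2 highest and 2 lowest members were also eligible, and a few of them are printed. Printed log2 ratios of single genes have nothing added. Shares of cells with a Myc UMI were taken with each cell thinned to 1500 UMIs. Gene positions came from the GENCODE annotation of the same mouse build, which matched 26646 of 27933 symbols.

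On simulated counts drawn at the real depth of all cells, genes made 4-fold higher had a median log2 ratio of 1.90 and genes made 2-fold higher 0.93, over 2697 genes, and the intervals of unchanged genes covered the true value in 95.5% of cases. In cycling cells the same medians were 1.90 and 0.94 over 2669 genes. Of 200 unchanged lists, 5% fell outside the central 95% of random lists over all cells and 3.5% in cycling cells. Each gene was drawn independently with counting error only, and the lists were randomly chosen genes, so these figures check the calculation only. They do not show how often lists of genes that vary together fall outside between libraries of different cell makeup.

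Alternatives were other cell filters, doublets kept or the highest doublet scores left out, Leiden resolutions 0.5 and 2, each library clustered alone, and several genes left out of or allowed in the clustering. Others were scaling outside ribosomal protein and mitochondrial genes, median-of-ratios size factors, the mean over cells, thinned cells, other minimum levels, a shared UMI floor, and the richest cells left out. The tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. The gene lists, markers, cell filter, clustering settings and naming rule were fixed before the data were examined.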

Results

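Single-cell RNA was measured in thymocytes, the developing T cells of the thymus, in 1 wild type library and 1 library homozygous for mutations in GATA sites 1 and 2 of NMe. NMe is a distant enhancer of the proto-oncogene Myc that the receptor NOTCH1 binds in T cell precursors, and GATA sites are motifs read by the transcription factor GATA3 in these cells. The libraries are called wild type and mutant here. The wild type library held 1346 cell barcodes with 6638880 unique molecular identifiers (UMIs) and a median of 3323.5 UMIs per barcode. The mutant library held 1737 barcodes with 6364506 UMIs and a median of 2596 UMIs. After filtering, 1338 wild type and 1726 mutant cells were kept. There was no replicate: with 1 library per group no test between genotypes exists, all intervals are 95% intervals that cover counting error only, and every comparison is between these libraries, not between the conditions. Log2 ratios are mutant over wild type.

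Myc, the gene that the mutated enhancer regulates, had a lower summed level in the mutant library. Its RNA is made from mm10 chromosome 15, positions 61985391 to 61990374. Over all cells, Myc was at 45.3 UMIs per 1000000 UMIs (CPM; interval 40.3 to 50.7, from 299 UMIs) in wild type and at 23.3 (19.7 to 27.4, from 147 UMIs) in mutant, a log2 ratio of -0.96 (-1.25 to -0.67). With every cell thinned to 1500 UMIs the ratio was -0.33 (-0.88 to 0.22), from 59 and 57 UMIs, an interval that included 0. The mutated sites lie outside the Myc transcript, so the reads cannot check which library carries the mutation. Pvt1, the gene next to Myc, had 10 UMIs in wild type and 19 in mutant, and its log2 ratio of 0.99 had an interval from -0.18 to 2.26. Both libraries held Xist, the RNA of the inactive X chromosome, at 1604 CPM in wild type and 1947 in mutant, and at most 1 UMI of each of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty.

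The thymocytes fell into 5 named classes that ran from early cells to mature T cells. Early CD4-CD8- cells (DN-like) were led by Il2ra, Hes1 and Myl10, and cycling cells by genes such as Ube2c, Cdc20, Hells and Mcm3. Resting CD4+CD8+ cells (DP-like) carried Rag1 and Cd8b1, cells signalled through their T cell receptor (post-selection-like) carried Itm2a, Cd5, Egr2 and Cd69, and single-positive cells (SP-like) carried Ccr7, Klf2 and S1pr1. The mutant library held more DN cells and fewer cycling cells. DN cells were 3.36% (2.46 to 4.47) of wild type cells, 45 cells, and 11.8% (10.3 to 13.4) of mutant cells, 204 cells. The difference was 8.46 percentage points (6.64 to 10.3). Cycling cells were 43.6% (40.9 to 46.3) of wild type and 16.7% (14.96 to 18.5) of mutant cells, 583 and 288 cells, a difference of -26.9 percentage points (-30.04 to -23.7). DP cells were 20.9% (18.7 to 23.1) of wild type and 27.5% (25.4 to 29.7) of mutant cells. This difference of 6.67 percentage points became -0.91 when both libraries had the same lower limit of UMIs per barcode. SP cells were 22.5% (20.3 to 24.8) and 29.95% (27.8 to 32.2). Post-selection cells were 7.47% (6.12 to 9.02) and 9.97% (8.59 to 11.5), and the sign of that difference depended on the clustering: it was -9.62 percentage points with each library clustered alone and -1.01 with NOTCH targets, early class markers and genes named by size left out of the clustering. Barcodes in the deposited tables started at 1781 UMIs in wild type and 1416 in mutant, and DP cells, with medians of 2121 and 1824 UMIs, lay nearest to these floors.

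**Figure D1:**
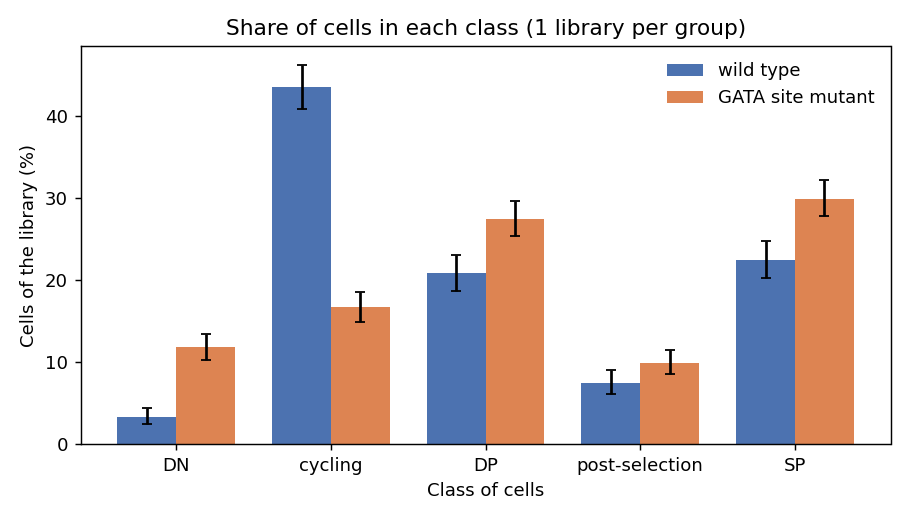
Share of kept cells in each class, in percent, with 1 bar per library and exact 95% binomial intervals. DN cells were 3.36% of wild type and 11.8% of mutant cells, and cycling cells 43.6% and 16.7%.

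The genes that define DN cells, such as Il2ra, also differed within other classes, so the clustering was repeated without NOTCH targets, early class markers and the genes named for the size of their ratio. DN cells were then 42 of 1338 in wild type and 177 of 1726 in mutant, and cycling cells 586 and 316. Without cell cycle genes and MYC targets in the clustering, cycling cells were 585 of 1338 in wild type and 313 of 1726 in mutant. Different clusters held most of some classes in the 2 libraries. In cycling cells, cluster 14, with the interferon-inducible gene Ifi202b among its leading genes, held 2 wild type and 157 mutant cells, whereas cluster 2, led by Tuba1c and Ube2c, held 145 and 21, and cluster 7, led by the histone gene Hist1h2af, held 142 and 6. In DP cells, cluster 0, led by Slc7a11 and Insl5, held 239 wild type and 24 mutant cells, and cluster 1, led by Lypd1 and Tctex1d1, held 21 and 431. A cluster mostly of 1 library may be that library and not a kind of cell.

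By class, Myc was lower in mutant DN and cycling cells and higher in mutant post-selection cells. In DN cells Myc was at 127 CPM (82.9 to 186) in wild type and 18.2 (9.97 to 30.6) in mutant, from 26 and 14 UMIs, a log2 ratio of -2.80 (-3.85 to -1.81). In cycling cells it was at 49.9 (43.5 to 57.1) and 19.3 (13.7 to 26.4), from 215 and 39 UMIs, a log2 ratio of -1.37 (-1.90 to -0.87). With thinned cells this ratio was -0.69 (-1.88 to 0.36), from 33 and 10 UMIs, an interval that included 0, and the DN ratio was -2.97 (-5.19 to -0.99). Within cluster 3, the cycling cluster with 224 wild type and 95 mutant cells, it was at 66.9 and 32.9, a log2 ratio of -1.02 (-1.79 to -0.32). Cluster 4, with Myc among its leading genes, gave 82 of the wild type cycling Myc UMIs and 3 of the mutant ones, from 70 and 9 cells. Within it Myc was at 88.1 and 69.2 CPM, a log2 ratio of -0.35 (-2.66 to 1.25). The cells of cluster 4 were unlike in the libraries, with median depths of 10189.5 and 2524 UMIs. Its median doublet score of 0.059 was second only to the 0.111 of cluster 16. In post-selection cells Myc was at 31.4 (14.4 to 59.7) in wild type and 70.2 (48.3 to 98.5) in mutant, a log2 ratio of 1.16 (0.06 to 2.41), with 44.4% of the 9 wild type UMIs in 1 cell. Most wild type cells of this class were in cluster 5 and most mutant cells in cluster 10, which was richer in Myc, and within clusters the intervals included 0: the ratio was 0.66 (-0.50 to 2.00) in cluster 10 and 1.53 (-2.11 to 7.25), from 1 and 3 UMIs, in cluster 5. The interval of the log2 ratio included 0 in DP cells, at -1.73 (-3.88 to 0.11), and in SP cells, at -0.42 (-1.06 to 0.22).

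**Figure D2:**
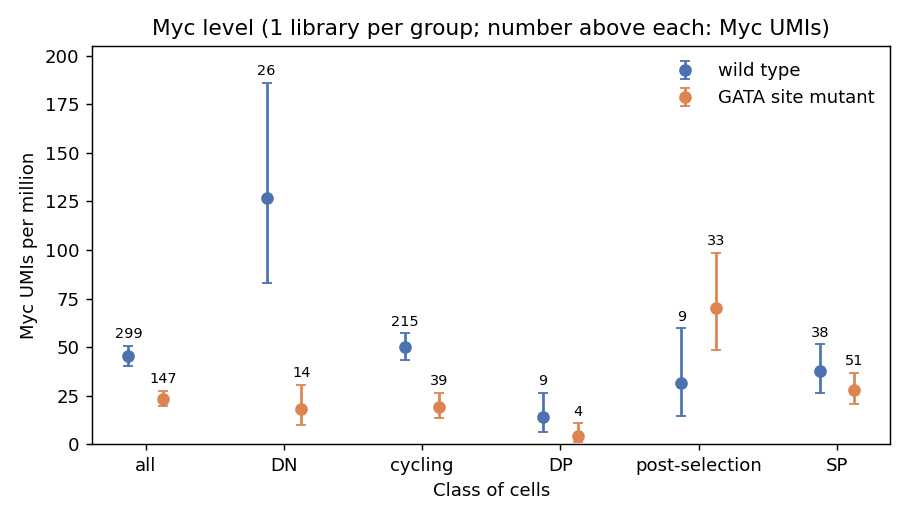
Myc CPM over all cells and in each class, with 1 point per library, exact 95% Poisson intervals and the number of Myc UMIs above each point. Myc was lower in mutant DN cells (18.2 against 127) and cycling cells (19.3 against 49.9) and higher in mutant post-selection cells (70.2 against 31.4).

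The share of cells with a Myc UMI was compared with every cell thinned to 1500 UMIs, which left out 0 wild type and 97 mutant cells. Over all cells the shares were 4.19% (3.18 to 5.40) and 3.01% (2.23 to 3.96), a difference not detectable at this depth, against 13.2% and 6.14% without thinning. In DN cells, 7 of 45 wild type cells, 15.6% (6.49 to 29.5), and 4 of 201 mutant cells, 1.99% (0.545 to 5.02), had a Myc UMI. Without thinning these shares were 37.8% and 6.86%. In cycling cells the shares were 5.15% (3.50 to 7.26) and 3.16% (1.45 to 5.91), a difference not detectable at this depth, against 19.7% and 8.68% without thinning. Post-selection cells had 2.00% (0.243 to 7.04) and 6.96% (3.53 to 12.1), and 5% and 9.88% without thinning. SP cells had 3.99% and 3.78%, and 9.30% and 7.93% without thinning. Resting DP cells, where Myc is low, had 1.79% (0.584 to 4.13) and 0.726% (0.150 to 2.11). In the mutant library the 1.99% of DN cells thus lay above the 0.726% of DP cells, with overlapping intervals. How much Myc comes from RNA free in the droplets was not measured. The DP shares were 3.23% and 0.842% without thinning. Median depths before thinning were 4225 and 3099 UMIs in DN cells, 5977 and 6090 in cycling cells, and 2121 and 1824 in DP cells.

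Over all cells, genes of dividing cells were lower in the mutant library, and NOTCH targets, T cell receptor response genes and interferon-inducible genes were higher. Of 41 DNA replication genes measured, 3 were higher and 38 lower, with a median log2 ratio of -0.49 at percentile 0 of 10000 random lists matched on level. Ccne2, a G1/S cyclin, was at 57.9 and 25.9 CPM, a log2 ratio of -1.16 (-1.43 to -0.89), and Clspn was at -1.02. All 48 mitosis genes measured were lower, with a median of -0.50 at percentile 0, which was -0.90 as a mean over cells and -0.92 in thinned cells. Mki67, the proliferation marker Ki-67, was at 186 and 96.2 CPM, a log2 ratio of -0.95 (-1.10 to -0.81), and Nusap1 was at -0.87. Of 10 NOTCH target and pathway genes, 9 were higher, with a median of 1.09 at percentile 100. Dtx1, a NOTCH target, was at 10.6 and 76.8 CPM, a log2 ratio of 2.86 (2.49 to 3.24), and Il2ra, the IL-2 receptor alpha chain, was at 23.8 and 137, a log2 ratio of 2.53 (2.28 to 2.78). Of 13 T cell receptor response genes, 12 were higher, with a median of 0.62 at percentile 100. Cd69 was at 1.47 and Nr4a1 at 1.14, and Id3 was lower at -0.38. All 13 interferon response genes were higher, with a median of 1.03 at percentile 100, among them Ifi203 at 2.17 and Usp18 at 2.01. These medians follow the shares of the classes as well as levels within cells.

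T-lineage transcription factors were also higher over all cells, and ribosomal protein genes were slightly lower. Of 20 T-lineage factors, 15 were higher, with a median of 0.34 at percentile 99.99. Lef1 was at 1.27 and Id2 at 0.93, and Tcf7 was lower at -0.27. All 8 CD3 and receptor signalling genes measured were higher, with a median of 0.39 at percentile 99.95, Cd3g at 0.69 among them. No receptor chain gene was among them. CDK inhibitors and quiescence genes had a median of 0.28 at percentile 99.2, with 7 of 10 higher. Klf2, a factor of resting T cells, was at 1.52, and Cdkn2c was lower at -0.85. Of 81 ribosomal protein genes, 70 were lower, with a median of -0.12 at percentile 0.48. V(D)J recombination genes had a median of -0.21 at percentile 2.31, with 5 of 7 lower and Rag1 at -0.54. MYC-activated ribosome biogenesis and growth genes had a median of -0.03 at percentile 2.55, within the central 95% of random lists, with 22 of 38 lower, Dctpp1 at -0.82, Tmem97 at -0.93 and Bop1, the highest, at 0.44.

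The remaining lists also lay within the central 95% of random lists over all cells. The medians were -0.06 for glycolysis, with 6 of 12 genes higher and Tpi1 at -0.77, -0.07 for oxidative phosphorylation, with 25 of 33 lower and Sdha at 0.31, and -0.08 for amino acid transport and polyamines, with 7 of 11 lower and Amd1 at -0.65. Apoptosis regulators had a median of 0.19, with 8 of 11 higher and Bcl2 at 1.44, p53 targets 0.20, with 6 of 7 higher and Ccng1 at 0.50, and tissue dissociation and stress genes 0.24, with 8 of 10 higher and Socs3 at 2.22. The unfolded protein response had a median of 0.25, with 8 of 10 higher and Ddit3 at 0.62, and the MYC network partners 0.24, with 4 of 6 higher and Mxi1 lower at -0.53. Translation factors, at 0.04 with Eef1b2 at -0.31, changed sign under both other scalings, and cholesterol synthesis genes, at 0.13 with Msmo1 at 0.46, were at -0.03 with median-of-ratios size factors. Such scalings shift all genes in the same direction. Relative to the median gene, translation factors were at -0.05 in the reported setting.

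Among the genes ranked by the size of their ratio over all cells, Ifi202b and the protease gene Ctse led the higher side, followed by Dtx1 and Il2ra. Ifi202b had 3 UMIs in wild type and 696 in mutant, a log2 ratio of 7.93 (6.37 to 10.21), and it belongs to 1 gene family with Ifi203, so the division of reads between the members is uncertain. Ctse was at 6.67 and 75.9 CPM, a log2 ratio of 3.51 (3.06 to 3.99), and Ctsl, another protease gene, at 89.5 and 394, a log2 ratio of 2.14 (2.01 to 2.27). Akr1c13 at 2.37, Cd200 at 2.24, Hes1 at 2.23, Cap1 at 1.79 and Myl10 at 1.79 were also higher. H2-Eb1 was at 2.06, with 45.5% of its wild type UMIs in 1 cell, and it is a leading gene of cluster 15, with 9 wild type and 43 mutant cells outside the 5 classes. On the lower side, Phlda1 was at -2.41 (-2.74 to -2.10), the mitochondrial protein gene Dnajc15 at -1.97 (-2.13 to -1.82), the tubulin gene Tubb2b at -1.58, Hist1h2af at -1.52, Prdx4 at -1.43, E2f2 at -1.26, Agtrap at -1.25, Tubb2a at -1.20 and Epsti1 at -1.16. Jchain had 844 wild type UMIs and 1 mutant UMI, and Slpi had 345 and 2, but 1 wild type cell gave 62.2% and 65.8% of these.

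DN cells of the mutant library had lower ribosomal protein, ribosome biogenesis and translation genes beside the lower Myc, and higher CD3 genes. In these cells the median gene was at a log2 ratio of 0.26, and at 0.02 when ribosomal protein and mitochondrial genes were left out of the scaling. All 81 ribosomal protein genes were lower, with a median of -0.43 at percentile 0, which was -0.69 relative to the median gene. Rpl10a was at -0.75 (-0.87 to -0.63). The nuclear RNA Malat1 was at 18623.6 CPM in wild type and 28809.6 in mutant DN cells. Of 42 MYC-activated genes, 31 were lower, with a median of -0.25 at percentile 0 and -0.51 relative to the median gene. The size of this median was unstable, from -0.60 to -0.16 under other settings, and -0.55 with the stricter cell filter. Slc19a1 and Ipo4, each at -2.23 (-4.56 to -0.01), were lowest. Translation factors and tRNA synthetases had a median of -0.29 at percentile 0.22, with 12 of 18 lower, among them Lars at -1.74 (-3.28 to -0.16). The amino acid transporter Slc7a1 was at -2.04 (-3.44 to -0.67). All 8 CD3 and receptor signalling genes measured were higher, with a median of 0.59 at percentile 99.2. Cd3g was at 1.37 (1.18 to 1.56) and Cd3d at 1.14 (0.94 to 1.34). T cell receptor response genes had a median of 0.74 at percentile 99.5, with 8 of 10 higher and Cd28 at 1.20 (0.33 to 2.19). Lef1 was at 1.58 (1.08 to 2.13). NOTCH targets are not compared in DN cells because Il2ra, Hes1, Dtx1 and Notch3 define the class.

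DNA replication, stress and cholesterol genes were higher in mutant DN cells. Of 34 DNA replication genes 29 were higher, with a median of 0.71 at percentile 100, or 0.67 with the gene that had 0 UMIs in 1 library at its bound. The replication factor gene 2810417H13Rik (Pclaf) had 5 and 170 UMIs, a log2 ratio of 3.18 (1.93 to 4.82). Tissue dissociation and stress genes had a median of 0.83 at percentile 99.9, or 0.70 at the bound, with 9 of 12 higher and Ier2 with 5 and 53 UMIs. Cholesterol synthesis genes had a median of 0.70 at percentile 97.6, with 11 of 12 higher and Dhcr7 at 3.14 (0.56 to 8.48), from 1 wild type UMI. Only 45 wild type DN cells stood behind these values, and stage and other cell type markers differed within the class. Cycling markers summed to 2241 and 5330 CPM, DN markers to 1226 and 2438, B cell markers to 737 and 1501, and innate-like T and NK markers to 117 and 324. Macrophage markers differed most among these, at 151 and 934 CPM, and in the mutant DN cluster 6 cells with over 20 UMIs of macrophage markers were present. The B cell list summed to 1520 and 1633 CPM in DP cells, so its sum need not mark B cells.

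Cycling cells of the mutant library had higher NOTCH targets, receptor response genes and interferon genes, and lower ribosomal protein genes. Clusters 2, 3, 4 and 7 made up most of this class in wild type and clusters 3 and 14 in mutant, and cell cycle genes, which define it, are not compared. Stage markers also differed within the class: DN markers summed to 193 and 384 CPM, resting DP markers to 4213 and 3115, post-selection markers to 468 and 884, and innate-like T and NK markers to 210 and 416. The median gene was at 0.19, and at 0.05 with ribosomal protein and mitochondrial genes left out of the scaling. All 10 NOTCH target and pathway genes measured were higher, with a median of 1.21 at percentile 100 and 1.02 relative to the median gene. This list shares Il2ra, Hes1, Dtx1, Notch3 and Ptcra with the DN markers, so it is not separate from their sum. Dtx1 was at 2.79 and 63.4 CPM, a log2 ratio of 4.51 (3.65 to 5.50), and Lef1 at 106 and 498, a log2 ratio of 2.23 (2.07 to 2.39). Of 16 T-lineage factors 12 were higher, with a median of 0.41 at percentile 99.94. Gata3, the factor that reads GATA sites in T cells, was at 70.4 and 182 CPM, a log2 ratio of 1.37 (1.15 to 1.59), and Id3 was at -1.44 (-1.70 to -1.19). T cell receptor response genes had a median of 0.72 at percentile 99.99, with 7 of 8 higher and Tox2 at 6.71 (4.16 to 12.04), from 1 and 49 UMIs. CD3 and receptor signalling genes had a median of 0.33 at percentile 98.0, with 7 of 8 higher and Cd3e at 0.50. Interferon response genes had a median of 0.95 at percentile 100, with 7 of 8 higher and Usp18 at 4.02 (2.96 to 5.30).

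Of 81 ribosomal protein genes in cycling cells, 79 were lower, with a median of -0.45 at percentile 0 and -0.64 relative to the median gene. Rps12 was at -0.75, and Malat1 was at 7879.6 and 10179.9 CPM. MYC-activated genes had a median of 0.10 at percentile 3.02, with 23 of 38 higher, but the sign changed to -0.06 when ribosomal protein and mitochondrial genes were left out of the scaling and to -0.07 with median-of-ratios size factors. Such scalings shift all genes in the same direction, and relative to the median gene the list was at -0.09 in the reported setting. In this list Gnl3 was at -0.62 and Bop1 at 1.14. Amino acid transport and polyamine genes had a median of -0.02 at percentile 1.76, with 7 of 12 lower and Amd1, a polyamine enzyme gene, at -1.58 (-2.15 to -1.05). Ranked by size, Ifi202b had 2 and 388 UMIs, a log2 ratio of 8.69 (6.83 to 11.74), and Ctse was at 3.76, Ifi203 at 3.32, Ctsl at 2.32, Smim5 at 2.13, Bcl2 at 2.05, Gsn at 1.99, Ctage5 at 1.93 and Cap1 at 1.92. Cd200 had 14 and 140 UMIs. Lower were Epsti1 at -3.10 (-3.85 to -2.43), Phlda1 at -2.63, Cd4 at -2.03 (-2.43 to -1.65), Dnajc15 at -1.62, Ccr9 at -1.42, Nsg2 at -1.31, Hist1h4i at -1.31, Rag1 at -1.14, Prdx4 at -1.12 and Cd8a at -1.08 (-1.20 to -0.97).

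DP cells of the mutant library had higher NOTCH targets and interferon genes and lower ribosomal protein and mitosis genes. The wild type cells were mostly in cluster 0 and the mutant cells mostly in cluster 1, and DN markers summed to 228 and 430.0 CPM, innate-like T and NK markers to 163 and 250.5, and cycling markers to 3310.2 and 2777. Of 9 NOTCH target and pathway genes, a list that shares members with the DN markers, 8 were higher, with a median of 1.00 at percentile 100. Dtx1 was at 7.69 and 65.8 CPM, a log2 ratio of 3.10 (1.80 to 4.77), Notch3 at 1.44 (0.36 to 2.68) and Tcf7 lower at -0.46. All 11 interferon genes were higher, with a median of 1.34 at percentile 100, Rtp4 at 1.92 (0.74 to 3.32) among them. Of 81 ribosomal protein genes 78 were lower, with a median of -0.28 at percentile 0 and Rpl10a at -0.54, and Malat1 was at 34204 and 45319 CPM. Of 21 mitosis genes 16 were lower, with a median of -0.81 at percentile 0 and Birc5 at -1.85 (-2.78 to -0.97), but this median was above 0 under 4 other settings. Among the genes ranked by size, Lypd1 had 0 and 163 UMIs. Slc15a2 had 0 and 50, at least 11.3-fold higher against a floor of 3 UMIs over the class. Tmem121 was at 4.69 (2.79 to 7.76), Ctse at 4.33 (2.74 to 6.64), Cd200 at 4.10 and Ctsl at 2.78 (2.51 to 3.06). Epsti1 was at -4.80 (-5.83 to -3.93), Tmem108 at -3.92, the cystine transporter gene Slc7a11 at -3.77, Dnajc15 at -3.02, Insl5 at -2.63 and Tubb2b at -2.17. Lypd1, Slc7a11, Insl5, Tubb2b and Ctsl were also among the leading genes of clusters 0 and 1, which they help to define.

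Post-selection cells of the mutant library had higher interferon genes and tissue dissociation and stress genes and lower recombination and mitosis genes. Cluster 5, led by Cd5 and Itm2a among others, held 61 wild type and 73 mutant cells, and cluster 10, led by Nr4a1 and Tnfrsf4, held 39 and 99. Other markers also differed within the class: regulatory T cell markers summed to 1565 and 2524 CPM, B cell markers to 237 and 459, and resting DP markers to 3433 and 2458. The regulatory T list shares Ikzf2 and Tnfrsf9 with the markers of this class. Among its 10 leading genes, cluster 10 had 4 post-selection markers and 3 regulatory T markers, shared genes included. All but 1 of 12 interferon genes were higher, with a median of 0.95 at percentile 100, and Ifi203 was at 1.49 (0.61 to 2.48). Tissue dissociation and stress genes had a median of 0.29 at percentile 99.3, with 7 of 10 higher and Ier2 at 0.73. Receptor response genes, which overlap the markers of this class, are not compared. Of 8 V(D)J recombination genes 7 were lower, with a median of -0.62 at percentile 0.31 and Rag1 at -1.41 (-2.27 to -0.58). Of 17 mitosis genes 13 were lower, with a median of -0.63 at percentile 0 and Ccnb2 at -3.18 (-6.39 to -0.98), from 11 and 2 UMIs. All 4 cholesterol genes measured were lower, with a median of -0.90 at percentile 0.37 and Sc5d at -1.89 (-4.04 to -0.04), but the sign changed under 3 other settings. Klf2 was at 2.32 (1.37 to 3.43). By size, Ctse was at 3.64 (1.70 to 6.73), and 1 mutant cell gave 38.3% of the mutant UMIs of Ly6a, 40.7% of H2-Eb1, 20% of Nkg7, 35.6% of H2-Aa and 36.7% of Nrgn. Dck was lower at -1.85 (-3.10 to -0.72), Nudt5 at -1.79 and H1f0 with 37 and 13 UMIs. All 69 wild type UMIs of the chemokine gene Ccl17 and all 20 of Gcg came from 1 cell each, and 98.6% of the 74 of Ccl22.

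SP cells of the mutant library had lower mitosis and recombination genes and slightly higher DNA replication and glycolysis genes. Resting DP markers in this class summed to 1953 and 1449 CPM, cycling markers to 4524 and 3977, and macrophage markers to 72.9 and 129.7. Of 25 mitosis genes 21 were lower, with a median of -0.33 at percentile 0. Ube2c was at -1.48 (-2.00 to -0.98) and Cenpf at -1.31, but the list median was 0.43 with the highest doublet scores left out. Of 5 V(D)J recombination genes 4 were lower, with a median of -0.49 at percentile 0.11, Rag1 at -1.59 (-2.20 to -1.01) and Dntt at -1.15 (-1.57 to -0.74). Of 29 DNA replication genes 24 were higher, with a median of 0.24 at percentile 99.8 and Atad2 at 0.94, with an interval above 0, but the median was -0.28 with each library clustered alone. Glycolysis genes had a median of 0.25 at percentile 99.4, with 10 of 12 higher and Tpi1 at 0.52 (-0.08 to 1.14). NOTCH targets were at 0.04 and interferon genes at 0.12, both within the central 95% of random lists. By size, Ctse was at 2.37 (1.64 to 3.18), Ctsl at 1.78 (1.01 to 2.64), Cap1 at 1.51, Fam3c at 1.49 and Rgs3 at 1.24. Ccl5 had 7 and 123 UMIs, with 43.9% of the mutant UMIs in 1 cell, and its direction reversed under 3 other settings. Pink1 was at -1.49 and Ly6d had 78 and 57 UMIs. Jchain had 832 UMIs in wild type and 0 in mutant, and Slpi 338 and 2, with 63.1% and 67.2% of the wild type UMIs in 1 cell. Under 10 other settings Slpi reversed, to between 0.21 and 0.34, and Jchain lay between -0.99 and -0.55, so the values of both genes depended on the setting.

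**Figure D3:**
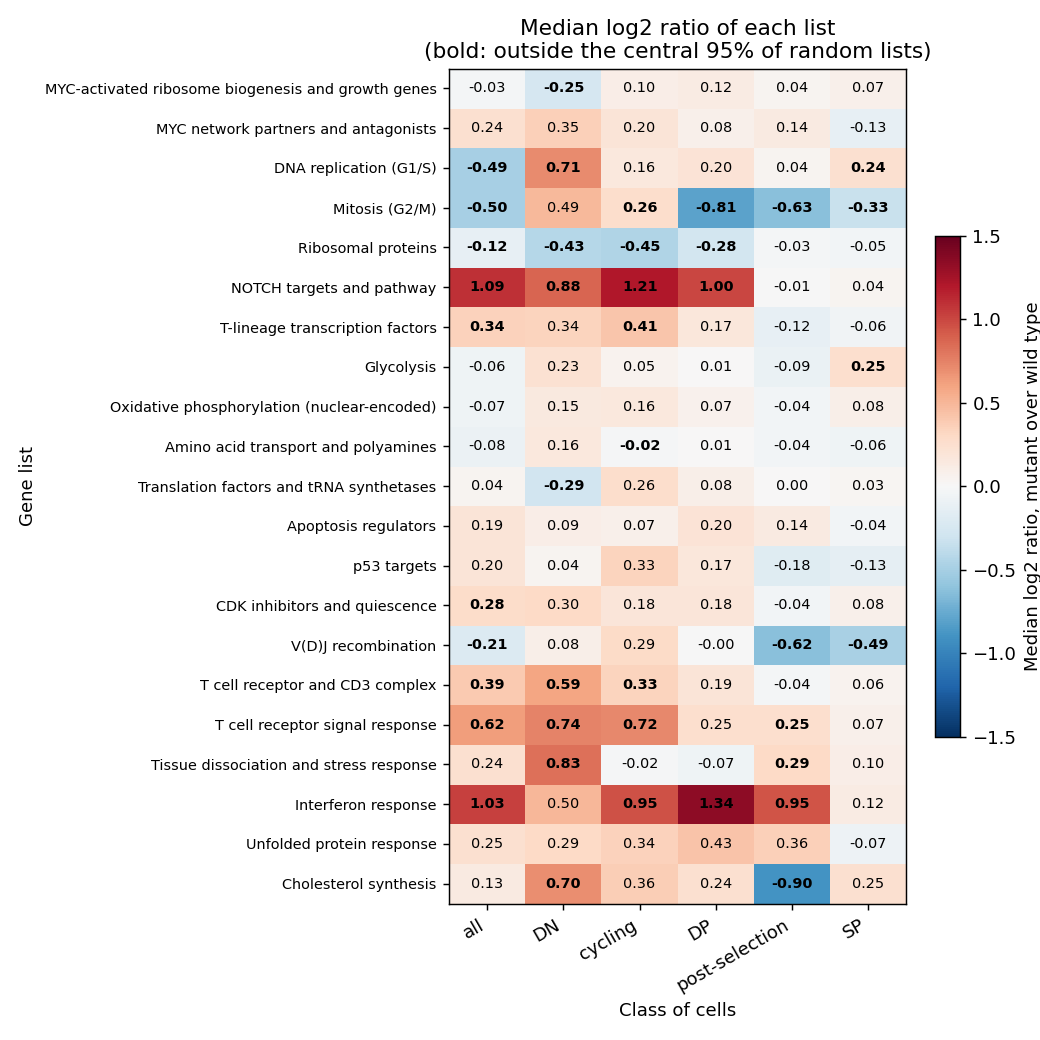
Median log2 ratio, mutant over wild type, of each gene list over all cells and in each class, with medians outside the central 95% of random lists in bold. NOTCH targets were at 1.21 in cycling and 1.00 in DP cells, and ribosomal protein genes at -0.43 in DN and -0.45 in cycling cells. MYC-activated genes in cycling cells, at 0.10, changed sign to -0.06 and -0.07 under the other scalings, which shift all genes in the same direction. Lists that define a class are drawn for it but not compared.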

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

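The test within cluster 3 and the shared UMI floor were chosen only after the result was seen.

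Myc differed in opposite directions between classes. Its log2 ratio was 1.16 in post-selection cells, against -2.80 in DN cells and -1.37 in cycling cells. The difference between classes was not tested. The post-selection value rested on 9 wild type and 33 mutant UMIs. Only 5 wild type cells held those 9 UMIs, 44.4% of them in 1 cell. Without the 3 cells richest in Myc of each library few wild type UMIs were left, and the log2 ratio was 2.60. Within cluster 10 it was 0.66 (-0.50 to 2.00) and within cluster 5 1.53 (-2.11 to 7.25), so the difference may follow the clusters that make up the class.

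For the lower Myc in DN and cycling cells, the tables argue against a few Myc-rich wild type cells as the whole cause: without the 3 richest wild type cells the DN ratio was -2.27 (-3.41 to -1.14), from 16 and 14 UMIs. They also argue against the different clusters of the cycling class as the whole cause, since Myc was at -1.02 (-1.79 to -0.32) within cluster 3, though within the Myc-rich cluster 4, with 70 wild type and 9 mutant cells, it was at -0.35 (-2.66 to 1.25), so cluster makeup may be a part of it. Depth per cell hardly differed over the cycling class, with medians of 5977 UMIs in wild type and 6090 in mutant, though within cluster 4 they were 10189.5 and 2524. Thinning could not decide about depth in cycling cells: the ratio was then -0.69 (-1.88 to 0.36), from 33 and 10 UMIs. That interval holds both 0 and the unthinned -1.37, so the 2 cannot be told apart with so few UMIs. As a mean over cells, which gives each cell equal weight, the cycling ratio stayed within its counting interval of -1.90 to -0.87. In DN cells the thinned ratio was -2.97 (-5.19 to -0.99). Stage markers also differed within these classes: DN markers summed to 1226 and 2438 CPM in DN cells, and resting DP markers to 4213 and 3115 in cycling cells. With each library clustered alone, 0 of 1338 wild type cells were placed in a DN cluster. Whether stage within a class underlies the Myc difference was not tested. Lower Myc through the mutated enhancer sites and a difference between the animals also remain possible explanations that 1 library per group leaves open.

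The mitosis genes also differed in opposite directions. Their median log2 ratio was 0.26 in cycling cells, against -0.81 in DP cells, -0.63 in post-selection cells and -0.33 in SP cells. These differences between classes were not tested. Mitosis genes define the cycling class, so its value also follows which cells were placed there. In DP cells the median was 0.32 with a shared UMI floor, and in SP cells 0.43 with the highest doublet scores left out, so in those classes the direction may rest on a few cells.

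Fewer cycling and more DN cells in the mutant library could come from the libraries' different UMI floors. With 1 shared floor of 1781 UMIs, cycling cells still differed by -21.8 percentage points (-25.3 to -18.3), and DN cells were 3.36% and 11.2%. Among cells of at least 4000 UMIs, far above both floors, the cycling difference was -36.5 percentage points (-42.0 to -30.7). Both values argue against the floors as the whole cause. A difference between 2 animals or cell preparations cannot be told apart from the genotype, because there was 1 library per group, and an effect of the mutated sites is equally open.

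Cluster 15, led by the antigen presentation genes Cd74, H2-Aa and H2-Eb1 and the B cell genes Cd79a and Ebf1, was left out of the 5 classes but is part of the comparisons over all cells. It held 2.49% (1.81 to 3.34) of mutant cells, 43 cells, and 0.673% of wild type cells, 9 cells. It drew attention as a signal outside the thymocyte classes.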

How the results depend on the processing

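The shared UMI floor, the leaving out of the highest doublet scores, of the cells richest in Myc or in a named gene, and of NOTCH, early class and named genes from the clustering were chosen only after the result was seen. No paired analysis was possible because each group had 1 library and no test was made. Of 3656 values under alternatives, 3389 kept the sign of the reported value, 3116 stayed within its counting interval or spread, 494 moved beyond it with no called sign changed, and 46 reversed. Where values moved or reversed, the cause was not tested.

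Lower Myc over all cells, in DN cells and in cycling cells kept its direction under every alternative in which it was taken: 16 values from -1.08 to -0.33, 15 from -3.06 to -2.23 and 15 from -1.66 to -0.69. No cycling ratio was taken with cell cycle genes and MYC targets left out of the clustering. Higher Myc in post-selection cells ranged from 1.00 to 2.60, lower Myc in DP cells from -3.15 to -1.25, and the SP ratio from -0.87 to 0.09. Where both libraries had a DN cluster, the DN share difference lay between 6.87 and 8.46 percentage points. Over all settings in which they were taken, also with each library clustered alone, the cycling difference lay between -26.9 and -21.6 and the SP difference between 5.39 and 12.6. NOTCH targets in DP cells lay between 0.83 and 1.14. With thinned cells, Myc was at -0.33 (-0.88 to 0.22) over all cells and -0.69 in cycling cells. Without the 3 richest cells it was at 2.60 in post-selection cells, where only 5 wild type cells had held a Myc UMI. Without thinning, the differences in the share of cells with a Myc UMI were -7.01 percentage points over all cells, -30.9 in DN and -11.0 in cycling cells. With each library clustered alone, 0 of 1338 wild type and 167 of 1726 mutant cells, 9.68%, were placed in a DN cluster, outside the DN range above, and no DN ratios could be had. With a shared floor the Myc ratio in DP cells could not be had.

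Shares moved with the clustering and the floor. With each library clustered alone, the differences were -21.6 points for cycling, 9.94 for DP, -9.62 for post-selection, reversed, and 12.6 for SP cells. With a shared UMI floor they were -21.8 for cycling, -0.91 for DP, reversed, and 11.9 for SP cells. For post-selection cells the difference was 0.43 at Leiden resolution 2 and -1.01, reversed, without NOTCH, early class and named genes.

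Ribosomal protein genes stayed lower in DN and cycling cells under all 16 alternatives each. In DN cells the median was -0.39 with no cell filter, the stricter filter, doublets kept, thinned cells, Leiden resolution 0.5, the shared floor and NOTCH, early class and named genes left out, and -0.40 as a mean over cells. It was -0.69 with scaling outside ribosomal protein and mitochondrial genes and -0.60 with median-of-ratios size factors. In cycling cells it was -0.42 with no cell filter, the stricter filter, thinned cells and the highest doublet scores left out, -0.43 with Leiden resolution 2, the mean over cells and the NOTCH, early class and named genes left out, -0.41 with the shared floor, -0.32 with each library clustered alone, -0.61 outside ribosomal protein and mitochondrial genes and -0.63 with median-of-ratios size factors.

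MYC-activated genes stayed lower in DN cells in 16 alternatives: -0.55 with the stricter filter, -0.54 without cell cycle and MYC genes in the clustering, -0.60 outside ribosomal protein and mitochondrial genes, -0.53 with median-of-ratios size factors, -0.43 as a mean over cells, -0.45 with the shared floor, -0.48 without the highest doublet scores and -0.57 without NOTCH, early class and named genes. In cycling cells they changed sign to -0.055 outside ribosomal protein and mitochondrial genes and to -0.068 with median-of-ratios size factors. These scalings shift all genes in the same direction, and the median gene moved from 0.19 to 0.046 and 0.032. MYC-activated genes in cycling cells were at 0.26 with each library clustered alone, 0.26 as a mean over cells and 0.29 in thinned cells. NOTCH targets in cycling cells were at 1.53 with each library clustered alone, 1.45 in thinned cells and 0.72 with no minimum level.

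Over all cells, DNA replication and mitosis genes stayed lower under 17 alternatives each. They were at -0.55 and -0.58 outside ribosomal protein and mitochondrial genes, -0.61 and -0.61 with median-of-ratios size factors, -0.60 and -0.90 as a mean over cells, -0.57 and -0.92 in thinned cells, and -0.41 and -0.42 with the shared floor.

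Other lists reversed as follows. Mitosis genes in DN cells were at -0.10 with the stricter filter, -0.16 at Leiden resolution 0.5, -0.043 with the shared floor and -0.12 without NOTCH, early class and named genes. In DP cells they were at 0.18 with the stricter filter, 0.011 at Leiden resolution 2, 0.022 with each library clustered alone and 0.32 with the shared floor, and in SP cells at 0.43 without the highest doublet scores. Oxidative phosphorylation genes were at -0.11 and -0.020 in DN cells, and at -0.0011 and -0.015 in cycling cells, outside ribosomal protein and mitochondrial genes and with median-of-ratios size factors, and at -0.016 in thinned SP cells. Those 2 scalings shift all genes in the same direction. Relative to the median gene the list was already at -0.108 in DN and -0.033 in cycling cells in the reported setting. With median-of-ratios size factors, cholesterol genes were at -0.027 over all cells, and DNA replication genes at -0.0063 and CDK inhibitors at -0.0025 in cycling cells. With each library clustered alone, the unfolded protein response was at -0.022 and cholesterol genes at 0.10 in post-selection cells, and DNA replication genes at -0.28 in SP cells. Post-selection cholesterol genes were also at 0.21 with no minimum level and 0.25 without NOTCH, early class and named genes. Ribosomal protein genes in post-selection cells were at 0.021 with the shared floor and 0.014 without the highest doublet scores, where T cell receptor response genes were at -0.020.

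Single genes that rest on a few cells reversed too. Slpi in SP cells was at 0.29 with no cell filter, 0.32 with the stricter filter, 0.30 with doublets kept, 0.30 at Leiden resolution 0.5, 0.34 at resolution 2, 0.30 with each library clustered alone, 0.33 without cell cycle and MYC genes, 0.30 with the shared floor, 0.21 without the highest doublet scores and 0.32 without NOTCH, early class and named genes. Ccl5 in SP cells was at -0.25 at Leiden resolution 0.5, -0.37 with each library clustered alone and -0.45 without the highest doublet scores. With each library clustered alone, Ly6a was at -0.94 and Nrgn at -0.077 in post-selection cells. Ccl22 there was at 0.40 without the richest cell of each library. With a minimum of 20 CPM, 15 of the 24 genes named over all cells, 14 of 24 in cycling, 10 of 12 in DP, 11 of 12 in post-selection and 4 of 12 in SP cells were shared with the reported ranking.

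Depth limited the Myc values: DN cells held 26 and 14 Myc UMIs, DP cells 9 and 4.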

Other observations

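The tests of the protease ratio and of neighbours among the genes named by size were chosen only after the result was seen.

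Regulatory T cell markers, as a sum over all cells, were at 281 CPM in wild type and 658 in mutant. This list shares Il2ra with the DN markers, and Ikzf2 and Tnfrsf9 with the post-selection markers. Innate-like T and NK markers were at 267 and 407, and cluster 13, led by Xcl1, Klrd1 and Ccl5, held 21 wild type and 27 mutant cells. Gamma-delta T markers were at 79.4 and 81.6, with 5 of their genes, Trdc among them, absent from the gene symbols. Markers of the classes themselves were at 219 and 563 for DN, 26465 and 15726 for cycling, 4429.7 and 3895 for DP, 1097 and 1956 for post-selection, and 6123 and 10813 for SP cells.

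Marker lists of cells other than T cells were also summed over all cells, but these sums need not mark such cells. B cell markers summed to 1520 and 1633 CPM within DP cells, and thymic epithelial markers to 703 and 642 within DN cells. The dendritic list shares Ccr9 with the resting DP list. Over all cells, B cell markers were at 855 and 1209 CPM, dendritic markers at 803 and 1167, macrophage markers at 172 and 308, thymic epithelial markers at 279 and 340.4, mesenchymal and endothelial markers at 66.8 and 85.9, erythroid markers at 9.09 and 8.57, and granulocyte markers at 1.06 and 0.794. Macrophage markers within DN cells had 31 UMIs in wild type and 717 in mutant, including Lyz2, C1qa and Apoe. The 5 richest of the 204 mutant DN cells gave 80.5% of these UMIs, and 6 of the 204 held more than 20 each.

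Nuclear Malat1 was at 16462 CPM in wild type and 27141 in mutant over all cells, 18623.6 and 28809.6 in DN cells, 7879.6 and 10179.9 in cycling cells, 34204 and 45319 in DP cells, 41995 and 41589 in post-selection cells, and 33414.5 and 31643 in SP cells. Ribosomal protein genes were lower in the mutant library in DN, cycling and DP cells, where Malat1 was higher, and whether the nuclear share of the RNA differed was not tested. Nnt, a gene that differs between laboratory strains, was at 37.3 and 31.6 CPM. A like level of 1 gene cannot show that the libraries share a strain background. Ifi202b had 3 UMIs in wild type and 696 in mutant over all cells, and whether strain underlies this was not tested.

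Some genes differed in the same direction in cycling, DP and SP cells, by at least 1 on the log2 scale and at 30 CPM or more. Of 3142 genes measured, these were Ctse, Akr1c13, Ctsl, Gm10093, Cap1 and Smo, all higher in mutant, and Dnajc15, lower. Free RNA from 1 source is argued against as the whole origin of both proteases together. The ratio of Ctsl to Ctse UMIs in the mutant library was 14 in DP and 0.627 in SP cells. This was a log2 difference of 4.48 (4.005 to 4.96). Ctsl had 1246 and 99 UMIs in these classes and Ctse 89 and 158, from 958172 and 1827467 UMIs of all genes. The ratio thus differed mostly through Ctsl, so it leaves free RNA open for Ctse. DNA of another strain, or DNA carried along with the mutation, may underlie such differences and cannot be told apart from the genotype. None of the 7 lay on the chromosome of Myc, and 0 lay within 5 Mb of another, but random sets of 7 had a median of 0 as well, so the count could not have come out lower. Of the 48 genes named by size in these classes or over all cells, 7 had an unrelated neighbour among them, where random sets had a median of 12, from 4 to 20, so there was no excess of neighbours. Among these, Dnajc15 and Epsti1 start at positions 77820681 and 77904239 of chromosome 14, and both were lower in cycling cells, at -1.62 and -3.10, and in DP cells, at -3.02 and -4.80. With no excess, the pair leaves open whether DNA of another strain lies there, and scattered strain differences need not lie close together.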
